A study of Mus musculus with 19 samples.

How the data were processed

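The series measured gene expression in locus coeruleus tissue of mice by RNA sequencing, with 19 libraries in 4 groups: WT_S6 (n = 4), WT_SD6 (n = 5), CnB1KO_S6 (n = 5) and CnB1KO_SD6 (n = 5). S6 stands for sleep and SD6 for 6 h of sleep deprivation. WT are the control mice and CnB1KO those with the knockout of the regulatory subunit of calcineurin, with tissue taken 4 weeks after injection of a virus that carries Cre into neurons. Whether both genotypes share a genetic background is not given in the sources used here. The libraries were prepared from poly(A) RNA without strand information, so counts of overlapping genes on opposite strands are uncertain. The labels give no batch, day or litter, so no comparison within batches was possible.

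The authors deposited counts per gene for all libraries in 1 table and FPKM per library in 4 tables, 1 per group. The submitters' processing notes name FastQC 0.12.1, Trim Galore 0.6.10, Picard 2.18.29, SAMtools 1.6, HTSeq 2.0.4, StringTie 2.2.1 and the genome build GRCm38, without a role or order. The aligner, the annotation release and the handling of duplicates are not given in the sources used here. The deposited counts were whole numbers for 14443 gene symbols, each with at least 381 counts summed over the 19 libraries, a mean of at least 20.05. Symbols without counts include abundant ones, such as mt-Co2 (5731 ± 574 FPKM in WT, SD, n = 9), and the rule that left them out is not given in the sources used here. Of these, 3161 symbols were tested by FPKM alone. The deposited FPKM (fragments per kilobase and mapped total, by the authors) held 62533 to 62551 lines for 3 groups and 59380 for WT_S6, so levels compared across the 4 tables assume the same processing. Symbols with several lines were left out of FPKM comparisons. Positions came from the GENCODE M21 annotation of GRCm38, in which 97.6% of the symbols matched 1 gene.

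The total count per library was 6260061 to 7002015 in WT_S6, 5606129 to 7903253 in WT_SD6, 3887298 to 7128244 in CnB1KO_S6 and 5110285 to 6966490 in CnB1KO_SD6. The highest count was 10665. The median slope of a gene's log2 count on the log2 library total fell from 1.31 for genes under 25 counts per kilobase of exon to 0.28 above 800, so counts of dense genes rose less than in proportion to depth. Within groups the spread between libraries was 1.38 to 19.1 times that of counting alone (chi-square per degree of freedom). The p-values cover the spread between libraries by 1 estimate per gene, shared by the 4 groups. No share is reported for a single library, so no binomial interval is given.

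Counts were scaled by TMM and tested with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood F test (2-sided), with all 19 libraries in 1 fit of the 4 groups (15 residual degrees of freedom, common dispersion 0.0121). The filter filterByExpr kept all 14443 genes. The 7 comparisons were deprivation in WT and in CnB1KO, CnB1KO against WT after sleep and after deprivation, their interaction, and the averages of both deprivation and both genotype comparisons. A gene passed at a Benjamini-Hochberg adjusted p under 0.05 over all genes. No covariate or block was used. Fold changes are the fitted ones, and CPM are TMM-scaled values per library with their mean and SD by group.

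The comparisons, tests, 31 gene lists, the rule for naming genes and the first group of alternatives below were fixed before the data were examined. The lists held 477 genes, 447 of them measured, and 14 were markers of cell types the dissected tissue could hold or of blood. They were immediate early genes, heat shock chaperones, endoplasmic reticulum chaperones, clock genes, glucocorticoid-responsive genes, calcineurin genes, kinases and phosphatases linked to sleep need, noradrenergic genes, wake-related receptors, synaptic genes, ion channels and cholesterol synthesis. Others were nuclear oxidative phosphorylation, ribosomal proteins, mitochondrially encoded transcripts (7 of 13 measured), interferon response, reactive glia (9 of 16 measured) and the marker lists named in the results. Lists were tested with camera from limma 3.58.1 on voom values with an estimated inter-gene correlation, adjusted over the 31 lists of a comparison. Beside it stand the members that passed over all genes and those that passed when adjusted over the list alone. A preset correlation of 0.01 and fry, which asks whether a list's genes move without comparing them with other genes, were alternatives.

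Genes were named by a rule. It took Ppp3r1 and, among genes with an adjusted p under 0.05 and a mean log2 CPM of at least 1, the 8 largest rises and 8 largest falls per comparison (5 for the averages and, where none passed, the 4 smallest p), without provisional symbols. It added up to 4 members of each list with a passing member or a passing test, and in both deprivation comparisons Fos, Arc, Homer1, Bdnf, Per1, Dbp, Cirbp, Rbm3, Th, Dbh, Slc6a2 and Gal. Of the genes so chosen 1 is not reported here. Overlaps were compared with the product of both counts over all genes and with Fisher's exact test (1-sided). The likeness of comparisons that share WT_S6 was compared with 100 simulations of unchanged groups and with WT_S6 split into 2 and 2 libraries.

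The alternatives were DESeq2-type size factors (RLE), no count filter, a filter of at least 1 CPM in at least 4 libraries, DESeq2 1.42.0, limma voom with sample quality weights and a fit of the compared groups alone. Further ones were a noradrenergic score (mean log2 CPM of 5 marker genes) or an oligodendrocyte score (the marker list) as covariate, and each library left out in turn. Chosen after the data were seen were the log2 library total as covariate, a cerebellar marker score as covariate, leaving out CnB1KO_S6 library 13 and WT_SD6 library 8 together (the lowest total and the lowest noradrenergic score), leaving out 1310 genes above 200 counts per kilobase, and limma on log2(FPKM + 0.1) for 14410 symbols.

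The pipeline was tested on simulated data at the depth and spread of these libraries, with 50 changed genes per fold. In the 4 pairwise comparisons it found 18% to 22% of 1.2-fold changes, 76% to 80% of 1.5-fold, 92% to 96% of 2-fold and 100% of 4-fold changes. For the interaction it found 2%, 60%, 84% and 98%, with 3 to 9 false calls per comparison. In 20 simulations without change 4.03% of list p-values lay under 0.05. Genes were drawn independently, so neither the false calls nor the list p-values cover structure that many genes share in the real libraries. Other splits of the real libraries, given at the end, called up to 1556 genes.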

Results

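The libraries were made from poly(A) RNA of locus coeruleus tissue, the brainstem nucleus whose noradrenergic neurons promote wakefulness, and were sequenced without strand information. They formed 4 groups by genotype and sleep. WT_S6 (n = 4) and WT_SD6 (n = 5) came from control mice that slept normally or were kept awake for 6 h. CnB1KO_S6 (n = 5) and CnB1KO_SD6 (n = 5) came from mice with a knockout of CnB1, the regulatory subunit of the calcium-activated phosphatase calcineurin. Tissue was taken 4 weeks after injection of a virus carrying Cre under a neuronal promoter. The total count per library ran from 3887298 to 7903253. Counts were given for 14443 genes. Levels are TMM-scaled CPM (counts brought to a common library total) with the SD between libraries, fold changes and adjusted p-values are from edgeR, and positions are on GRCm38.

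Ppp3r1, which encodes CnB1 and lies on chromosome 11 from 17159263 to 17200375, was the check of the genotype labels. Its level was 161 ± 4.08 (SD, n = 4) in WT_S6 and 152 ± 10.9 (SD, n = 5) in WT_SD6. It was 129 ± 13.2 (SD, n = 5) in CnB1KO_S6 and 133 ± 6.73 (SD, n = 5) in CnB1KO_SD6. Averaged over sleep states, Ppp3r1 was 1.2-fold lower in CnB1KO (adjusted p = 0.00758). After sleep all 5 CnB1KO libraries lay below all 4 WT libraries, a 1.25-fold difference that did not pass (adjusted p = 0.104). After deprivation 3 of 5 CnB1KO libraries lay below all 5 WT libraries, with a 1.15-fold difference that did not pass (adjusted p = 0.177). The difference after sleep passed with DESeq2 (adjusted p = 0.00204), with limma voom (adjusted p = 0.0016) and with the log2 library total as covariate (adjusted p = 6.5e-05). It also passed without CnB1KO_S6 library 13 (adjusted p = 0.00233, and 0.00368 where WT_SD6 library 8 was left out too). Ppp3r1 is among the genes above 200 counts per kilobase of exon. For genes of 200 to 400 the median slope of log2 count on log2 library total was 0.78. Its CPM can thus be too high in shallow libraries, of which CnB1KO_S6 library 13 is the shallowest, and the genotype difference too small. That after deprivation passed with the log2 library total as covariate (adjusted p = 0.00332). The averaged difference did not pass with an oligodendrocyte score as covariate (adjusted p = 0.0575), although its size was not smaller there. Over its 31 alternatives the adjusted p by these tools was 6.5e-05 to 0.494 after sleep and 0.00332 to 1.0 after deprivation, and over 30 for the average it was 5.3e-06 to 0.0575.

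**Figure D1:**
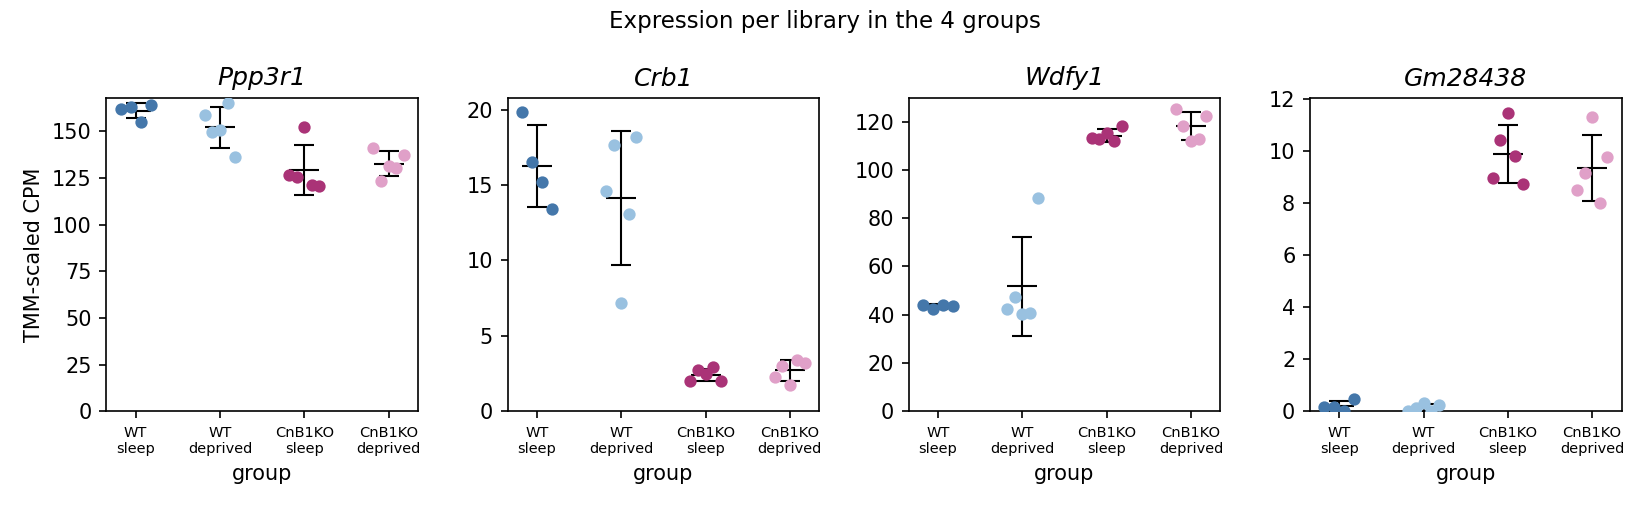
Expression of Ppp3r1, Crb1, Wdfy1 and Gm28438 in each library (points) of the 4 groups, in TMM-scaled CPM, with the mean and SD as bars. Crb1 lay between 7.15 and 20.1 CPM in the WT libraries and between 1.81 and 3.34 in the CnB1KO libraries before TMM scaling.

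Sleep deprivation in control mice addressed which transcripts follow prolonged waking in the locus coeruleus. Plin4, which codes for a lipid droplet coat protein, rose from 6.69 ± 2.34 (SD, n = 4) to 70.1 ± 47.4 (SD, n = 5) CPM, 10.5-fold (adjusted p = 0.00247). Cdkn1a, which encodes the cell cycle inhibitor p21, rose 2.49-fold (adjusted p = 8.7e-04), Map3k6, a stress kinase gene, 2.48-fold (adjusted p = 0.00946), and the dioxygenase gene Phyhd1 2.48-fold (adjusted p = 0.00159). Opalin, a gene of myelinating oligodendrocytes, fell from 43.4 ± 2.27 (SD, n = 4) to 17.8 ± 4.62 (SD, n = 5) CPM, 2.43-fold lower (adjusted p = 3.0e-04). All 5 deprived libraries lay below all 4 sleep libraries. Fam83d, Tmem52, Hspa1b and Stab2 rose by 2.32 to 2.58-fold. Ninj2, Abcc6, Col2a1, Pipox, Serpinb1a, Enpp6 and Pllp fell, being 1.7 to 2.26-fold lower. Enpp6 and Pllp are also expressed by oligodendrocytes. The mean log2 CPM of the oligodendrocyte markers was 7.24 ± 0.09 (SD, n = 4) in WT_S6 and 6.95 ± 0.11 (SD, n = 5) in WT_SD6.

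Of the gene lists fixed beforehand, glucocorticoid-responsive genes rose as a group in control mice. Of 18 measured members 10 rose and 0 fell, 18 rose when adjusted over the list alone, and the list passed (adjusted p = 0.0229 with an estimated correlation). Sgk1, a kinase gene induced by corticosterone, rose from 55.7 ± 5.6 (SD, n = 4) to 110.0 ± 16.1 (SD, n = 5) CPM (adjusted p = 0.00176), and Errfi1 rose 1.35-fold (adjusted p = 6.1e-04). Of 20 immediate early genes, which follow neuronal firing, 3 rose, 0 fell and 17 did not pass, 10 rose when adjusted over the list alone, and the list passed (adjusted p = 0.0229 with an estimated correlation). Dusp1 rose 1.88-fold (adjusted p = 0.00709), Bdnf, which encodes a neurotrophin, 1.51-fold (adjusted p = 0.00709) and Fosl2 1.57-fold (adjusted p = 0.0369). Fos, at 11.3 ± 3.44 (SD, n = 4) and 28.4 ± 8.36 (SD, n = 5) CPM, did not pass (adjusted p = 0.0562). Fos passed without CnB1KO_SD6 library 16 (adjusted p = 0.00598), with DESeq2 (adjusted p = 0.00813) and with limma voom (adjusted p = 0.0187). It also passed with a cerebellar score as covariate (adjusted p = 0.0109), and over all its alternatives the adjusted p was 0.00598 to 0.488. Of 21 endoplasmic reticulum chaperone and unfolded protein response genes 5 rose and 0 fell, 10 rose when adjusted over the list alone, and the list passed (adjusted p = 0.0321 with an estimated correlation). Sdf2l1 rose 1.83-fold, Manf 1.24-fold, Dnajc3 1.21-fold and Dnajb11 1.18-fold. This list did not pass without WT_S6 library 3 (adjusted p = 0.102) or WT_SD6 library 6 (adjusted p = 0.0801). Of 18 cytosolic heat shock chaperones 3 rose and 15 did not pass, 6 rose when adjusted over the list alone, and the list did not pass (adjusted p = 0.144 with an estimated correlation), except without CnB1KO_S6 library 13 (adjusted p = 0.0349). Counts of the abundant member Hspa8 rose little with depth, from 795 of 3887298 in that library to 987 of 7903253 in WT_SD6 library 10. Its CPM thus also follows the library total, and its missing call does not show an unchanged level. Its FPKM was 248.35 to 274.37 in WT_S6 and 272.37 to 352.09 in WT_SD6. Hspa1b rose 2.36-fold and Hspa1a 1.81-fold, a pair of near-identical genes between which the placement of reads is uncertain, and Chordc1 rose 1.25-fold.

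The clock genes moved both ways after deprivation in control mice. Of 19 measured members 2 rose, 2 fell and 15 did not pass, and 3 rose and 3 fell when adjusted over the list alone. The list did not pass (adjusted p = 0.993 with an estimated correlation). Its median log2 change was 0.00, its mean 0.04 and the direction of its test down. Per1 rose 1.33-fold and Npas2 1.5-fold, while Dbp, a clock output gene, was 1.37-fold lower and Per3 1.29-fold lower. Cirbp, which encodes a cold-inducible RNA-binding protein, fell from 79.6 ± 3.81 (SD, n = 4) to 56 ± 2.67 (SD, n = 5) CPM (adjusted p = 8.7e-04). The other genes chosen in advance did not pass: Arc (log2 change -0.07, adjusted p = 0.91), Homer1 (0.35, adjusted p = 0.109) and Rbm3 (-0.01, adjusted p = 0.991). Nor did the noradrenergic genes Th (0.03, adjusted p = 0.981), Dbh (-0.13, adjusted p = 0.876), Slc6a2 (-0.17, adjusted p = 0.864) and Gal (0.12, adjusted p = 0.93). Homer1 passed without WT_SD6 library 6 (adjusted p = 0.0405) and with the noradrenergic (adjusted p = 0.0396) or cerebellar score (adjusted p = 0.00952) as covariate, with a range of 0.00952 to 0.602 over its alternatives. Among the markers of other cell types, the astrocyte gene Gjb6 rose 1.36-fold while 10 of 11 astrocyte markers did not pass (adjusted p = 0.993 with an estimated correlation). Of 12 oligodendrocyte markers 2 fell, Opalin and Aspa, and 3 fell when adjusted over the list alone (adjusted p = 0.472 with an estimated correlation). Of 12 microglia markers 1 fell, Cx3cr1, and 2 fell when adjusted over the list alone (adjusted p = 0.44 with an estimated correlation).

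In all, 165 of 14443 genes passed in control mice, 112 higher and 53 lower after deprivation. The libraries of both groups did not overlap for 156 of the 165, against 5.21% of all genes and 1.59% by chance. Genes chosen for a small p in these libraries tend to be separated by the choice alone, here and in the comparisons below. The count was 35 in a fit of the 9 compared libraries alone, 49 with the oligodendrocyte score as covariate, 74 from FPKM, 295 with limma voom and 400 with the cerebellar score as covariate. It was 84, 78, 97 and 78 without WT_S6 library 1, 2, 3 or 4 and 99 without WT_SD6 library 9. Of the 35 genes named here that passed, 19 also passed without any 1 library. The calls of Abcc6, Aspa, Col2a1, Cx3cr1, Dnajb11, Enpp6, Fam83d, Fosl2, Ninj2, Npas2, Per1, Per3, Pipox, Pllp, Stab2 and Tmem52 ended without at least 1 library. Their highest adjusted p was 0.0531 to 0.186, and 18 of the 19 libraries ended at least 1 of these calls. The oligodendrocyte score ended 23 of the 35 calls, the fit of the compared libraries alone 23 and FPKM 14.

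**Figure D2:**
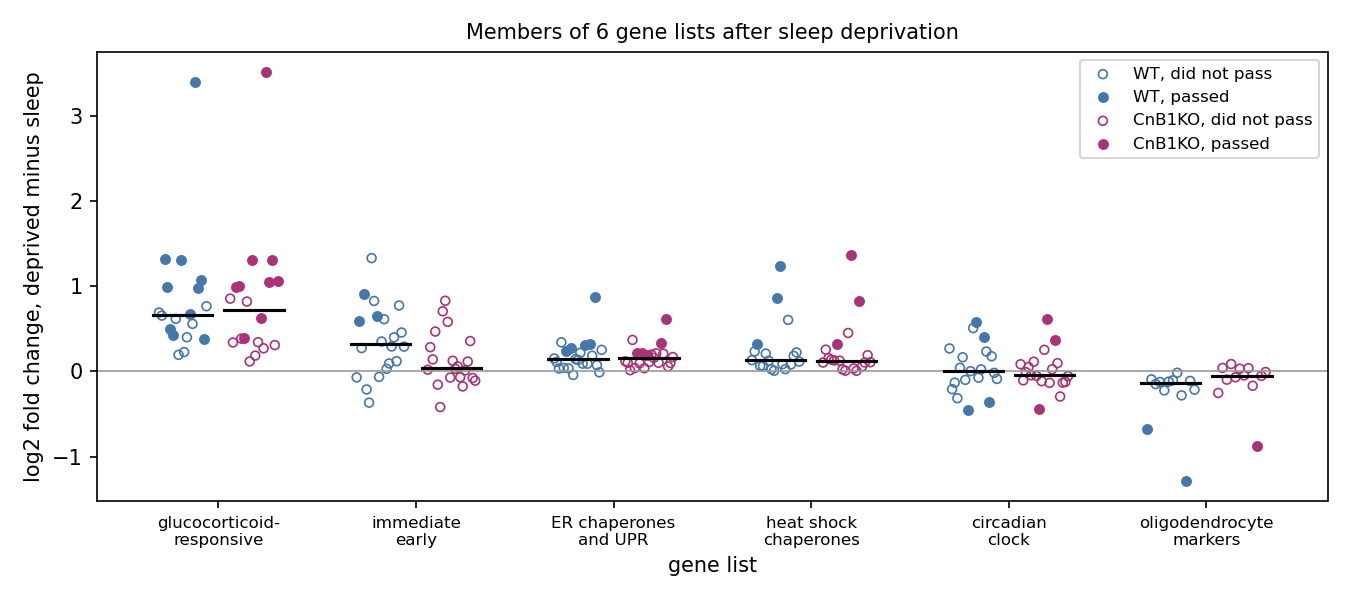
Log2 fold change of each measured member (points) of 6 gene lists after sleep deprivation in WT and in CnB1KO; filled points passed, and the bars are medians. The median of the glucocorticoid-responsive genes was 0.67 in WT and 0.72 in CnB1KO.

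Sleep deprivation in CnB1KO mice addressed which of these responses are seen in mice with the knockout. How far calcineurin was reduced in this tissue is not shown. Ppp3r1 RNA was lower in deprived CnB1KO than in deprived WT mice, but did not pass by edgeR (adjusted p = 0.177). Plin4 rose from 6.34 ± 1.41 (SD, n = 5) to 73.9 ± 25.2 (SD, n = 5) CPM, 11.4-fold (adjusted p = 0.0012), and Fam83d, which encodes a mitotic spindle protein, rose 4.42-fold (adjusted p = 7.5e-04). Hspa1b, with the uncertainty given above, rose 2.58-fold, Sult1a1, a sulfotransferase gene, 2.48-fold, Hif3a 2.48-fold, Map3k6 2.48-fold, Phyhd1 2.34-fold and Ccn2 2.27-fold. Opalin fell from 39.5 ± 3.18 (SD, n = 5) to 21.4 ± 3.86 (SD, n = 5) CPM, 1.83-fold lower (adjusted p = 0.00309). Abcc6, Prss35, Dcst1, Pipox, Klhdc9, Ednra and BC022960 also fell, being 1.52 to 1.95-fold lower.

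Glucocorticoid-responsive genes rose as a group here as well: 9 of 18 members rose and 0 fell, 14 rose when adjusted over the list alone, and the list passed (adjusted p = 0.0127 with an estimated correlation). Sgk1 rose from 55.7 ± 5.28 (SD, n = 5) to 116 ± 26.1 (SD, n = 5) CPM (adjusted p = 7.5e-04), and Errfi1 rose 1.31-fold. Of the endoplasmic reticulum chaperones 5 of 21 rose, 11 when adjusted over the list alone, and the list passed (adjusted p = 0.0127 with an estimated correlation). Sdf2l1 rose 1.54-fold, Pdia4 1.26-fold, Dnajb11 1.17-fold and Herpud1 1.14-fold. Of the 20 immediate early genes 0 passed by edgeR over all genes, 3 rose when adjusted over the list alone, and the list did not pass (adjusted p = 0.953 with an estimated correlation). Fos was at 10.6 ± 2.6 (SD, n = 5) and 17.7 ± 11.2 (SD, n = 5) CPM (adjusted p = 0.472). The log2 change of Bdnf was 0.29 (adjusted p = 0.293), of Arc 0.02 (adjusted p = 1.0) and of Homer1 0.13 (adjusted p = 0.816). Of the 18 heat shock chaperones 3 rose, Hspa1b, Hspb1 at 1.77-fold and Dnajb1 at 1.25-fold. When adjusted over the list alone 7 rose (adjusted p = 0.113 with an estimated correlation, and 0.00984 without CnB1KO_S6 library 13). Hspa8, with the limit of its counts given above, had 250.52 to 291.78 FPKM in CnB1KO_S6 and 311.38 to 357.38 in CnB1KO_SD6. Of the 19 clock genes Npas2 (1.53-fold) and Per1 (1.29-fold) rose and Dbp was 1.36-fold lower. When adjusted over the list alone 2 rose and 2 fell (adjusted p = 0.993 with an estimated correlation), with a median log2 change of -0.04 and a mean of 0.01. Per3 had a log2 change of -0.29 (adjusted p = 0.069). It passed without WT_SD6 library 7 (adjusted p = 0.0292) or CnB1KO_SD6 library 16 (adjusted p = 0.0228) and in 5 other alternatives, with a range of 0.0194 to 0.20.

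Cirbp was 1.37-fold lower after deprivation in CnB1KO (adjusted p = 0.00163). Rbm3 (log2 change -0.08, adjusted p = 0.976), Th (0.07, adjusted p = 1.0), Dbh (0.02, adjusted p = 1.0), Slc6a2 (-0.02, adjusted p = 1.0) and Gal (0.22, adjusted p = 0.919) did not pass. Among other cell types Gjb6 rose 1.32-fold, 1 of 11 astrocyte markers (adjusted p = 0.993 with an estimated correlation). Opalin was the 1 of 12 oligodendrocyte markers that fell (adjusted p = 0.993 with an estimated correlation). The oligodendrocyte score was 7.33 ± 0.19 (SD, n = 5) in CnB1KO_S6 and 7.22 ± 0.14 (SD, n = 5) in CnB1KO_SD6. In all 100 genes passed, 67 higher and 33 lower. For 94 of them the libraries of the groups did not overlap, against 2.66% of all genes and 0.794% by chance. The count was 66 from FPKM, 160 with DESeq2, 206 with limma voom, 163 with the noradrenergic score and 163 with the cerebellar score as covariate. It was 55, 62 and 54 without CnB1KO_S6 library 11, CnB1KO_S6 library 14 or CnB1KO_SD6 library 18. Of the 29 genes named that passed, 18 passed without any 1 library. The calls of Ccn2, Dcst1, Dnajb1, Dnajb11, Ednra, Herpud1, Hspb1, Klhdc9, Pdia4, Per1 and Pipox ended without at least 1 library. Their highest adjusted p was 0.0528 to 0.147, and 16 of the 19 libraries ended at least 1 of these calls. FPKM ended 6 of the 29 calls and the fit of the compared libraries alone 9.

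Set side by side, 66 genes passed in both genotypes in the same direction and 0 in opposite directions. Of these 51 were higher against 0.520 expected from the counts (Fisher's exact p = 3.2e-99) and 15 lower against 0.121 expected (Fisher's exact p = 3.3e-29). The genes that fell in both include Opalin, Abcc6, Pipox, Dbp and Cirbp. Of the 199 genes that passed in either genotype 198 had the same direction in both. The log2 fold changes correlated across all genes with r = 0.49, although genes are not independent replicates. For the 165 genes of the control mice the median log2 change, in the direction of control mice, was 0.48 there and 0.33 in CnB1KO. For the 100 genes of CnB1KO it was 0.46 in CnB1KO and 0.43, in the direction of CnB1KO, in control mice. Genes chosen for passing in 1 genotype tend to a smaller change in the other by the choice alone.

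**Figure D3:**
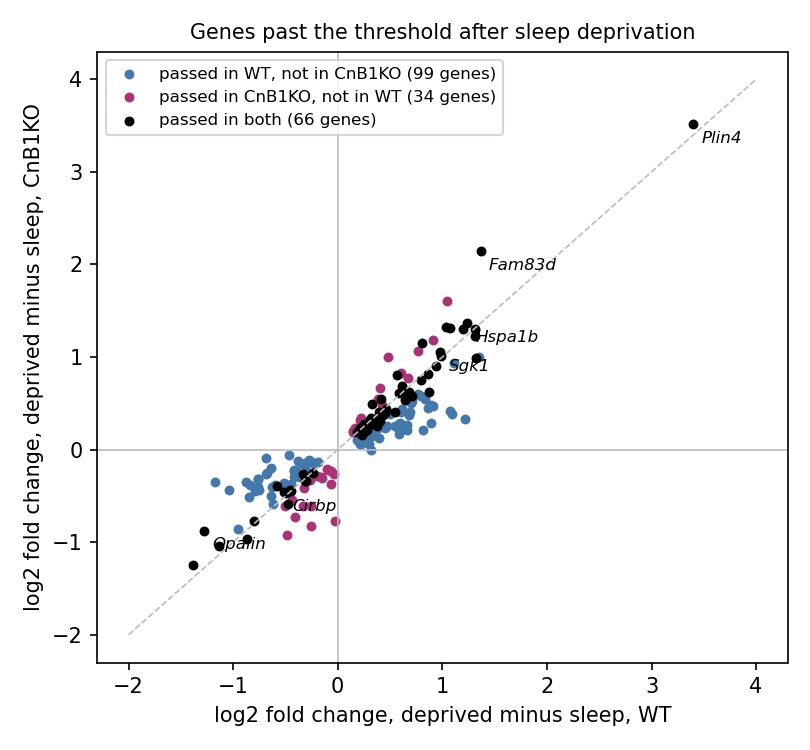
Log2 fold change after sleep deprivation in WT (horizontal) and CnB1KO (vertical) of the genes that passed in WT, in CnB1KO or in both; the dashed line marks equal change. The 66 genes that passed in both lie in the same direction on both axes.

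Whether the response differed between genotypes was tested by the interaction, in which 0 of 14443 genes passed by edgeR, with 287 genes at an unadjusted p under 0.05. By other tools 0 passed with limma voom and 1 with DESeq2. The 4 genes with the smallest p, none of which passed, were Gm15446 (log2 difference of the changes -0.74, adjusted p = 0.681), 1700063D05Rik (0.76, adjusted p = 1.0), Prob1 (0.52, adjusted p = 1.0) and Nfkb1. The latter, which encodes a subunit of the NF-κB transcription factor, had -0.23 (adjusted p = 1.0). Gm15446 passed with DESeq2 (adjusted p = 0.0362) and without CnB1KO_S6 library 11 (adjusted p = 0.00201), which gave a count of 1, with a range of 0.00201 to 1.0 over its alternatives. Genes looked up after their separate changes were seen were Fos, with a log2 difference of -0.62 and an SE of 0.46 (adjusted p = 1.0), Bdnf, with -0.31 and an SE of 0.15 (adjusted p = 1.0), and Opalin, with 0.41 and an SE of 0.20 (adjusted p = 1.0). The difference of Fos was -1.10 with an SE of 0.33 without CnB1KO_SD6 library 16 (adjusted p = 1.0). With the oligodendrocyte score as covariate that of Fos was -0.31 (adjusted p = 1.0) and that of Opalin 0.20 (adjusted p = 1.0). The immediate early genes had a median difference of -0.19, with a p of 0.0126 before adjustment over the 31 lists (adjusted p = 0.39 with an estimated correlation), and 0 of the 31 lists passed. The higher count in control mice is thus not shown to be a difference between genotypes. Nor do 0 calls show equal responses, since for the interaction 60% of simulated 1.5-fold and 2% of simulated 1.2-fold differences were found.

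Averaged over genotypes, 678 genes passed, 371 higher and 307 lower after deprivation. Plin4 (11-fold, adjusted p = 1.1e-05), Fam83d (3.37-fold), Tekt4 (2.85-fold), Map3k6 (2.48-fold) and Hspa1b (2.46-fold) rose most among the genes chosen by rule. Opalin (2.11-fold lower, adjusted p = 4.7e-06), Cd180 (1.93-fold lower), Abcc6 (1.89-fold lower) and Sgk2 (1.76-fold lower) were among those that fell most. Of the glucocorticoid-responsive genes 15 of 18 rose, 18 when adjusted over the list alone (adjusted p = 0.0133 with an estimated correlation), among them Sgk1, Errfi1 and Cdkn1a (1.33 to 2.23-fold). Of the endoplasmic reticulum chaperones 10 of 21 rose, 13 when adjusted over the list alone (adjusted p = 0.0133 with an estimated correlation), with Sdf2l1, Manf, Dnajc3 and Dnajb11 at 1.17 to 1.68-fold. Of the immediate early genes 5 of 20 rose, among them Fosb at 1.78-fold, Dusp1, Fosl2 and Bdnf, and 7 when adjusted over the list alone. Of the heat shock chaperones 6 of 18 rose, with Hspa1a, Hspb1 and Chordc1 at 1.18 to 1.64-fold, and 10 when adjusted over the list alone. Neither list passed (adjusted p = 0.0602 for each with an estimated correlation). The immediate early genes passed without WT_S6 library 2, WT_SD6 library 10 or CnB1KO_SD6 library 19 (adjusted p = 0.0415, 0.0359 and 0.0476). The heat shock chaperones passed without WT_S6 library 2 or CnB1KO_S6 library 13 (adjusted p = 0.0415 and 0.00868). Of the clock genes 3 rose and 2 fell, 3 and 4 when adjusted over the list alone (adjusted p = 0.953 with an estimated correlation), with Npas2 and Per1 higher and Dbp and Per3 lower. Of 21 cholesterol synthesis genes 4 fell, Lss, Mvk, Mvd and Dhcr7 (1.13 to 1.23-fold lower), and 5 when adjusted over the list alone, without a call for the list (adjusted p = 0.802 with an estimated correlation).

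Among markers of other cell types in the averaged response Gjb6 rose 1.34-fold (1 of 11 astrocyte markers). The oligodendrocyte markers Opalin, Aspa and Mog fell (3 of 12), as did the microglia markers Cx3cr1 and Siglech (2 of 12). Of 10 endothelial markers Ly6c1 rose 1.29-fold and Itm2a was 1.16-fold lower. Kcnn2, a calcium-activated potassium channel gene, rose 1.17-fold (1 of 23 ion channel genes), and the interferon-induced genes Xaf1 and Ifit3 fell (2 of 16). None of these lists passed (adjusted p = 0.953, 0.802, 0.953, 0.953, 0.953 and 0.802 in this order with an estimated correlation). The averaged count was 367 with the oligodendrocyte score and 1166 with the cerebellar score as covariate, and leaving out any 1 library kept it between 470 and 673. Of the 42 genes chosen by rule that passed, 36 passed without any 1 library. The calls of Cx3cr1, Ifit3, Itm2a, Kcnn2, Mog and Xaf1 ended without at least 1 library. Their highest adjusted p was 0.0655 to 0.117, and 18 of the 19 libraries ended at least 1 of these calls. The oligodendrocyte score ended 14 of the 42 calls and FPKM 8.

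Between CnB1KO and WT mice that slept 7 genes passed, 3 higher and 4 lower in CnB1KO. Genotype and genetic background cannot be told apart here, so these differences are not shown to follow from calcineurin loss. Crb1, a cell polarity gene on chromosome 1 from 139197056 to 139377100, fell from 16.2 ± 2.72 (SD, n = 4) to 2.43 ± 0.40 (SD, n = 5) CPM, 6.64-fold lower (adjusted p = 7.1e-06). Wdfy1, which encodes an endosomal adaptor protein and lies on chromosome 1 from 79702262 to 79776143, rose from 43.4 ± 0.849 (SD, n = 4) to 114 ± 2.58 (SD, n = 5) CPM (adjusted p = 4.2e-04). Klf2, a transcription factor gene of endothelial cells, rose 1.72-fold (adjusted p = 0.0378), and Aim2, which encodes a sensor of cytosolic DNA (chromosome 1, 173350879 to 173466040), was 2.42-fold lower (adjusted p = 0.0158). Meaf6, a histone acetyltransferase subunit gene, was 1.19-fold lower (adjusted p = 0.0444) and Snapc1 1.18-fold lower (adjusted p = 0.0378). The third gene that rose, Gm28438, is a pseudogene on chromosome 1 from 24612775 to 24613119 and was chosen after its values were seen. It had 0.194 ± 0.194 (SD, n = 4) in WT_S6 and 9.88 ± 1.11 (SD, n = 5) CPM in CnB1KO_S6 (adjusted p = 5.4e-08). Its FPKM did not show this difference, at 1294 ± 141 (SD, n = 9) in WT and 1169 ± 218 (SD, n = 10) in CnB1KO. Its sequence matches a mitochondrial gene, so the placement of its reads is uncertain.

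For all 7 genes the libraries of the groups did not overlap, against 4.32% of all genes and 1.59% by chance. None of the 31 lists passed. Of 10 endothelial markers 0 passed by edgeR over all genes and 8 rose when adjusted over the list alone (adjusted p = 0.826 with an estimated correlation). The endothelial score was 5.42 ± 0.09 (SD, n = 4) in WT_S6 and 5.69 ± 0.12 (SD, n = 5) in CnB1KO_S6. At an unadjusted p under 0.05 the comparison had 1456 genes. The count was 13 with DESeq2, 85 with limma voom, 19 with the log2 library total, 4 with the oligodendrocyte or the cerebellar score as covariate, 4 from FPKM and 3 in a fit of the compared libraries alone. It was 4, 3 and 3 without WT_S6 library 1, 2 or 4, 4 without WT_SD6 library 7, 3 and 3 without CnB1KO_S6 library 11 or 12 and 4 without CnB1KO_SD6 library 19. Of the 6 genes chosen by rule, Crb1 and Wdfy1 passed without any 1 library. The calls of Aim2, Klf2, Meaf6 and Snapc1 ended without at least 1 library, with a highest adjusted p of 0.081 to 0.365 per gene. Meaf6 did not fall in FPKM (log2 change 0.02, adjusted p = 0.985, with a range of 0.00103 to 0.985 over its alternatives).

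Between sleep-deprived CnB1KO and WT mice, with the same limit on the cause, 19 genes passed, 11 higher and 8 lower in CnB1KO, and 2197 had an unadjusted p under 0.05. Crb1 was at 14.1 ± 4.43 (SD, n = 5) CPM in WT_SD6 and 2.72 ± 0.686 (SD, n = 5) in CnB1KO_SD6, 5.25-fold lower (adjusted p = 2.9e-05). Wdfy1 was at 51.8 ± 20.6 (SD, n = 5) and 118 ± 5.83 (SD, n = 5) CPM (adjusted p = 0.0010). WT_SD6 library 10 had 88.2 CPM of Wdfy1, the others 40.2 to 47.5. Stc2, which encodes a secreted glycoprotein of the stress response, was 2.12-fold lower (adjusted p = 0.00108), and Plekhn1, Nmd3 and Snapc1 were 1.18 to 1.5-fold lower. Cd59a, which encodes an inhibitor of complement, rose 1.85-fold (adjusted p = 0.0158). Aif1l, Prob1, the proton pump subunit gene Tcirg1, Cpne9 and the cadherin gene Cdh22 rose by 1.21 to 1.49-fold. The 7 remaining genes carry provisional symbols, among them Gm28438 (adjusted p = 9.3e-09).

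For 18 of the 19 genes the libraries did not overlap, against 2.05% of all genes and 0.794% by chance. None of the 31 lists passed. When adjusted over the list alone 7 of 10 endothelial, 5 of 12 oligodendrocyte and 4 of 12 microglia markers rose (adjusted p = 0.647, 0.647 and 0.647 in this order with an estimated correlation). The count was 95 with DESeq2, 33 with limma voom, 32 with the log2 library total, 4 with the oligodendrocyte score as covariate and 7 from FPKM. It was 4 in a fit of the compared libraries alone and 12 without CnB1KO_S6 library 13 and WT_SD6 library 8. It was 220 without CnB1KO_SD6 library 16, and 12, 10 and 7 without CnB1KO_SD6 library 17, 18 or 19. It was 11 without WT_S6 library 3, 9 and 7 without WT_SD6 library 7 or 9, and 11, 12 and 11 without CnB1KO_S6 library 12, 13 or 14. Crb1, Wdfy1, Stc2 and Cdh22 passed without any 1 library. In the fit of the compared libraries alone Wdfy1, Stc2 and Cdh22 did not pass (adjusted p = 0.131, 0.0527 and 0.0767), nor did Stc2 and Cdh22 with the oligodendrocyte score as covariate (adjusted p = 0.0604 and 0.11). The calls of Aif1l, Cd59a, Cpne9, Nmd3, Plekhn1, Prob1, Snapc1 and Tcirg1 ended without at least 1 library, with a highest adjusted p of 0.0517 to 0.147 per gene. The oligodendrocyte score ended 10 of these 12 calls.

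The genotype effects after sleep and after deprivation shared 4 genes in the same direction, Gm28438 and Wdfy1 higher (0.00228 expected, Fisher's exact p = 1.6e-06) and Crb1 and Snapc1 lower (0.00222 expected, Fisher's exact p = 1.6e-06). Averaged over sleep states, 447 genes passed, 272 higher and 175 lower in CnB1KO, most of them by little, with a median change of 0.23 on the log2 scale. The excess of higher genes depended on the setting. Higher and lower genes numbered 218 and 187 with RLE size factors, 122 and 122 without CnB1KO_SD6 library 18, and 893 and 509 with limma voom. Beyond Crb1, Aim2, Stc2, Wdfy1 and Cd59a, the rule named Or51e2, an olfactory receptor gene (2.47-fold), Fblim1 (1.83-fold) and Colq, which encodes the collagen tail of acetylcholinesterase (1.78-fold), as higher. It named Slc16a11 (1.64-fold lower) and Fndc9 (1.64-fold lower) as lower. Of 10 endothelial markers 6 rose and 9 did when adjusted over the list alone, with Flt1 and Cldn5 at 1.28 to 1.29-fold, Egfl7 at 1.2-fold and Slco1a4 at 1.17-fold. Of 11 mural and meningeal markers Pdgfrb, Rgs5 and Vtn rose. Of 12 oligodendrocyte markers Ermn, Ugt8a and Mag rose, with 9 when adjusted over the list alone, and of 12 microglia markers C1qa and C1qc. None of these lists passed (adjusted p = 0.732 for each with an estimated correlation). The potassium channel genes Kcnn1 and Kcnn2 and the pacemaker channel gene Hcn2 rose 1.19 to 1.43-fold, 3 of 23 ion channel genes (adjusted p = 0.932 with an estimated correlation).

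Among immediate early genes in the averaged genotype comparison Arc was 1.36-fold, Klf4 1.43-fold and Jun 1.1-fold higher and Bdnf 1.23-fold lower (4 of 20 passed; adjusted p = 0.932 with an estimated correlation). Per1 was 1.19-fold lower (1 of 19 clock genes), the small heat shock gene Cryab 1.18-fold and the cytokine receptor gene Osmr 1.51-fold higher. Of the 23 calcineurin subunits, regulators and targets 3 passed, Ppp3r1, Mef2c at 1.3-fold lower and Nfatc2, a transcription factor that calcineurin activates, at 1.17-fold higher (adjusted p = 0.732 with an estimated correlation). The averaged count was 694 with DESeq2, 1402 with limma voom, 173 from FPKM, 10 with the oligodendrocyte and 278 with the cerebellar score as covariate. Leaving out 1 library moved it by more than 1.5 times to 239, 194 and 76 (WT_S6 library 2, 3 and 4) and to 144, 204 and 744 (WT_SD6 library 7, 9 and 10). Without 1 CnB1KO library it moved to 147, 296, 777 and 118 (CnB1KO_S6 library 12, 13, 14 and 15) and 1088, 251, 244 and 172 (CnB1KO_SD6 library 16, 17, 18 and 19). Of the 34 genes named that passed, besides Ppp3r1, 12 passed without any 1 library (Wdfy1, Cd59a, Crb1, Aim2, Stc2, Fndc9, Klf4, Arc, Kcnn1, Flt1, Cldn5 and Egfl7) and 22 did not. The oligodendrocyte score ended 30 of these calls, leaving Wdfy1, Crb1, Aim2 and Stc2, FPKM 19 and the cerebellar score 12.

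The knockout effect after sleep and the deprivation response of control mice share the WT_S6 libraries, which alone produces a positive correlation. Across genes their log2 fold changes correlated with r = 0.27 and a covariance of 0.00998, against a mean r of 0.55 (0.52 to 0.60) and a covariance of 0.0157 in 100 simulations of unchanged groups. With WT_S6 split so that no library was shared, the mean r over 6 splits was -0.07 (-0.38 to 0.07). The mean covariance over these splits was -0.00499 (-0.0279 to 0.00303). The observed r and covariance lay below those of all 100 simulations (lowest covariance 0.0141). Effects in opposite directions or libraries unlike the simulated ones could each give this, and they were not told apart. The splits left 2 WT_S6 libraries per comparison, and their r varied in sign. Neither reference thus shows that both effects are alike beyond the shared controls, and whether they oppose each other is not decided.

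The remaining lists had no member past the threshold in any of the 7 comparisons and did not pass in any (lowest adjusted p with an estimated correlation in brackets): the kinases and phosphatases linked to sleep need (0.877), noradrenergic neuron genes (0.728) and wake-related receptors (0.953). So it was for synaptic genes (0.728), nuclear oxidative phosphorylation (0.728), cytosolic ribosomal proteins (0.728) and mitochondrially encoded transcripts (0.728). The same held for markers of oligodendrocyte precursors (0.728), choroid plexus and ependyma (0.869), cerebellar neurons (0.728), serotonergic neurons (0.728), cholinergic neurons (0.801), GABAergic and glycinergic neurons (0.731), glutamatergic and parabrachial neurons (0.732), all neurons (0.728) and for red blood cell genes (0.728). The reactive glia list (lowest adjusted p = 0.728) had Osmr as its only called member. Counts of dense genes rose less than in proportion to depth, so for abundant members of any list a missing call does not show an unchanged level.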

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

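Of the tests below, those of an inherited block around Ppp3r1, of the reads and the mitochondrial copy of Gm28438, of the amount of mitochondria and of chromosome 1 were chosen after the result was seen, as was the use of FPKM for genes without counts.

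Crb1, Wdfy1, Aim2 and Gm28438 differed between CnB1KO and WT by more than Ppp3r1, the targeted gene; averaged over sleep states their log2 differences were -2.56, 1.29, -1.08 and 5.68, against -0.26 for Ppp3r1. The tables argue against a block inherited with the target, since 0 of the 4 genes lie within 20 Mb of Ppp3r1, and against a change in the amount of mitochondria, since the median log2 FPKM difference of 34 mitochondrial genes was 0.082 (-0.319 to 0.28), leaving out mt-Nd3 (-0.166) and its neighbours mt-Tg (-1.833) and mt-Tr (-0.844). For Gm28438 a candidate explanation is a mitochondrial sequence difference between the mice of both genotypes: its sequence differs from mt-Nd3 over 345 bases by T3C alone (positions from 1 at the start of the mt-Nd3 transcript), its counts were 0 to 3 per WT library and 42 to 78 per CnB1KO library while its FPKM differed by a log2 value of -0.146, and mt-Tg beside mt-Nd3 differed by -1.833 in log2 FPKM. A difference of genetic background could also bear on Crb1, Wdfy1 and Aim2, which lie on chromosome 1 with Gm28438: 4 of 21 genes called after sleep or after deprivation lie there, against 844 of 14101 tested (Fisher's exact p = 0.03375, 1-sided), but times the 22 chromosomes, a correction added after this p was seen because the chromosome was picked after the genes, it is 0.742. These 4 are the genes that prompted the test, and they include Gm28438, whose reads may be mitochondrial. A difference of background also need not gather on 1 chromosome. The test therefore does not decide on such a difference. An effect of calcineurin loss stays open, as genotype and genetic background cannot be told apart here: over the 10 CnB1KO libraries Crb1 and Ppp3r1 had r = -0.01877 (permutation p = 0.958; rho = -0.0303, permutation p = 0.946; r = 0.153 without the 2 libraries farthest in Ppp3r1) and Wdfy1 and Ppp3r1 r = 0.337 (permutation p = 0.340; rho = 0.273, permutation p = 0.449; r = 0.247 without those 2), with adjusted p = 0.958 and 0.681 for r over both genes.

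The following libraries stood apart from the rest of their group, in 18 of 232 groups of values examined over 53 genes, the totals and the scores, where chance marks about 1 in 20. CnB1KO_S6 library 13 had a total of 3.887 M counts (M, mega) against 6.234 to 7.128 M in the others, and 152.3 CPM of Ppp3r1 against 120.4 to 126.6. CnB1KO_S6 library 12 had a noradrenergic score of 6.446 against 7.01 to 7.184 and 19.22 CPM of Gal against 30.02 to 34.3. CnB1KO_SD6 library 16 had an oligodendrocyte score of 6.976 against 7.246 to 7.301, 37.43 CPM of Fos against 11.15 to 15.61, 48.06 CPM of Rbm3 against 37.34 to 38.23 and 34.0 CPM of Cd59a against 41.25 to 43.51. In WT_SD6, library 8 had 111 CPM of Dbh against 186.4 to 219.7. Library 9 had 12.55 CPM of Enpp6 against 24.69 to 31.14 and 3.637 CPM of Prss35 against 5.639 to 6.204. Library 10 had 88.23 CPM of Wdfy1 against 40.24 to 47.47 and 29.78 CPM of Tcirg1 against 23.49 to 24.3. In WT_S6, library 4 had 27.15 CPM of Arc against 36.88 to 39.06. Library 2 had 29.47 CPM of Hif3a against 15.88 to 17.58 and 42.13 CPM of Wdfy1 against 43.65 to 43.97, and library 1 had 26.48 CPM of Plekhn1 against 33.94 to 34.77. CnB1KO_SD6 library 20 had 2.19 CPM of Dcst1 against 4.487 to 5.721.

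Among 3161 symbols with FPKM but no counts, tested with limma on log2(FPKM + 0.1), 1 passed for deprivation in WT: ENSMUSG00000120522 was lower by a log2 difference of -1.106 (adjusted p = 0.00795; 17 ± 2.07 FPKM in WT_S6, SD, n = 4, and 7.89 ± 1.4 in WT_SD6, SD, n = 5). For deprivation in CnB1KO 2 passed, Fbxw23 with 3.251 (adjusted p = 0.00955; 0.248 ± 0.141 and 2.97 ± 0.967 FPKM, SD, n = 5 each) and Gm43089 with 5.818 (adjusted p = 0.00364). Gm43089 was listed at 0 in all 5 CnB1KO_S6 libraries and at 5.7 ± 1.3 FPKM (SD, n = 5) in CnB1KO_SD6. Neither difference between genotypes passed, as 0 of the 3161 symbols passed for the interaction by limma. Between genotypes Clic3 passed after sleep with -1.305 (adjusted p = 0.0455; 2.45 ± 0.539 FPKM in WT_S6, SD, n = 4, and 0.951 ± 0.366 in CnB1KO_S6, SD, n = 5). The mitochondrial transfer RNA genes mt-Tg and mt-Tr passed after sleep with -1.925 and -0.8082 and after deprivation with -1.794 and -0.8462. Averaged, 27 symbols passed for deprivation (18 higher, 9 lower) and 6 for genotype (2 higher, 4 lower).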

How the results depend on the processing

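Of the alternatives, those with the cerebellar score or the log2 library total as covariate, without CnB1KO_S6 library 13 and WT_SD6 library 8, without dense genes and from FPKM were chosen after the data were seen. No paired analysis was possible because the numbers of the libraries are not those of the titles and name no litter or pair. No filter and the filter of 1 CPM kept the same 14443 genes and so changed nothing by construction. Where not stated otherwise below, the cause was not tested.

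Counts of passing genes in the original analysis were 165 for deprivation in WT, 100 in CnB1KO, 7 for genotype after sleep, 19 after deprivation, 0 for the interaction, 678 for deprivation averaged and 447 for genotype averaged. Those that moved by over 1.5 times are given next. With DESeq2 they were 160 for deprivation in CnB1KO, 13 and 95 for genotype after sleep and after deprivation, 1 for the interaction and 694 for genotype averaged. With limma voom they were 295 and 206 for deprivation in WT and CnB1KO, 85 and 33 for genotype after sleep and after deprivation and 1402 averaged. In a fit of the compared groups alone they were 35 for deprivation in WT and 3 and 4 for genotype after sleep and after deprivation. Deprivation in CnB1KO, at 70, did not move by over 1.5 times. This fit has fewer libraries and no spread shared with other groups. Pairs of WT_SD6 libraries differed by up to 19.1 times counting alone, pairs of CnB1KO_SD6 libraries by up to 7.44. The shared spread may thus be too small for WT_SD6, which was not tested. With the noradrenergic score the count for deprivation in CnB1KO was 163. With the oligodendrocyte score counts were 49 for deprivation in WT, 367 for deprivation averaged, 4 for genotype after sleep, 4 after deprivation and 10 averaged. With the cerebellar score they were 400 and 163 for deprivation in WT and CnB1KO, 1166 averaged, 4 for genotype after sleep and 278 averaged. With the log2 library total they were 19 and 32 for genotype after sleep and after deprivation. Without CnB1KO_S6 library 13 and WT_SD6 library 8, 12 passed for genotype after deprivation. From FPKM they were 74 and 66 for deprivation in WT and CnB1KO, 4 and 7 for genotype after sleep and after deprivation and 173 averaged. RLE size factors and leaving out dense genes moved no count by over 1.5 times. Leaving out each library in turn gave 78 to 176 for deprivation in WT, 54 to 134 in CnB1KO, 3 to 8 for genotype after sleep, 7 to 220 after deprivation, 0 to 1 for the interaction, 470 to 673 for deprivation averaged and 76 to 1088 for genotype averaged.

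Ppp3r1 was lower in CnB1KO in all alternatives of the genotype comparisons. After sleep its log2 difference of -0.32 passed with DESeq2 (-0.33), limma voom (-0.37), the log2 library total (-0.37) and without libraries 13 and 8 (-0.39), and was -0.39 to -0.30 without each library in turn. After deprivation it passed with the log2 library total alone (-0.25). Averaged, it did not pass with the oligodendrocyte score (-0.29).

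The 1 called gene that turned was Meaf6 for genotype after sleep, at 0.0176 from FPKM (adjusted p = 0.985). All other turns were of genes that did not pass before or after. With the oligodendrocyte score these were for deprivation in WT Arc (0.15), Dbh (0.0271) and Mag (0.0983), for deprivation in CnB1KO Slc6a2 (0.0372) and Cnp (0.0122), for deprivation averaged Ppp3r1 (0.0139) and Mag (0.0794), and for genotype averaged Serpina3n (-0.0131) and Mal (-0.00189). Without libraries 13 and 8 they were Dbh (0.0025) in WT, Arc (-0.0106), Slc6a2 (0.0533) and Cnp (0.0172) in CnB1KO, and Ppp3r1 (0.00631) for deprivation averaged. Others for deprivation were Th (-0.0159) from FPKM in WT and, in CnB1KO, Th (-0.0262) and Dbh (-0.0372) with the cerebellar score, Dbh (-0.00479) with the noradrenergic score and Slc6a2 (0.0766) with limma voom. Without each library in turn the changes in WT ran from -0.0878 to 0.0667 for Rbm3, -0.0896 to 0.20 for Th, -0.22 to 0.00906 for Dbh and -0.0156 to 0.28 for Gal. Those in CnB1KO ran from -0.047 to 0.0778 for Arc, -0.0319 to 0.12 for Th, -0.0816 to 0.12 for Dbh, -0.13 to 0.0536 for Slc6a2 and -0.16 to 0.0172 for Cnp, and that of Ppp3r1 for deprivation averaged from -0.0366 to 0.00819.

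Passing lists among 31 numbered 3 for deprivation in WT, 2 in CnB1KO, 2 averaged and 0 in the 4 other comparisons. With a preset correlation of 0.01 they numbered 8, 5 and 8, and 7 for genotype after sleep, 13 after deprivation, 14 averaged and 5 for the interaction. With fry 4 passed for deprivation in WT, 3 in CnB1KO and 4 averaged, and 1 for genotype averaged. With fry in either direction they numbered 6, 4 and 9 for deprivation, 1 for genotype after deprivation and 7 averaged. Without each library in turn 2 to 4 passed for deprivation averaged. At an adjusted p under 0.1, a looser limit by construction, 112 genes passed in both deprivation comparisons in place of 66. With WT_S6 split, so that the comparisons no longer share libraries, the correlation of the genotype difference after sleep with the change in WT fell from 0.267 to -0.0681.

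Of 231 named results 159 had passed. Of these 92 passed without any 1 library and 67 did not, while 11 of the 72 others passed without at least 1. Calls ended for 85 with the oligodendrocyte score, 55 from FPKM, 27 without libraries 13 and 8, 19 with the cerebellar score, 12 with the noradrenergic score, 8 with the log2 library total, 4 with RLE size factors, 2 with limma voom, 1 of 146 without dense genes and 0 with DESeq2. In the fit of the compared groups alone, possible for 82 of the calls, 47 ended. At the depth, spread and group sizes of these libraries together, 18% to 22% of simulated 1.2-fold changes were found in the pairwise comparisons and 2% for the interaction. What depth alone limits was not tested apart.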

Other observations

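Of the tests below, that of linked genes and the alternatives with the cerebellar score or the log2 library total as covariate were chosen after the data were seen.

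Levels of cell type markers differed between libraries. Whether this follows what each dissected piece held or a change in the tissue itself was not tested apart. The mean log2 CPM of 5 noradrenergic genes was 6.81 ± 0.42 (SD, n = 4) in WT_S6, 6.62 ± 0.60 (SD, n = 5) in WT_SD6, 6.96 ± 0.29 (SD, n = 5) in CnB1KO_S6 and 7.01 ± 0.24 (SD, n = 5) in CnB1KO_SD6. That of the markers of cerebellar neurons, which lie beside the nucleus, was 6.04 ± 0.82 (SD, n = 4), 6.00 ± 1.42 (SD, n = 5), 5.42 ± 0.94 (SD, n = 5) and 5.10 ± 1.32 (SD, n = 5) in the same order, from 3.39 to 7.32 over all libraries. Endothelial markers were at 5.45 ± 0.12 (SD, n = 5) in WT_SD6 and 5.69 ± 0.16 (SD, n = 5) in CnB1KO_SD6.

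Of gene lists in which 0 members passed for genotype, 15 of 16 measured interferon-response and MHC class I genes had a positive log2 difference between CnB1KO and WT averaged over sleep states, with a median of 0.30. Of them 0 passed by edgeR over all 14443 genes, 8 rose when adjusted over the list alone, and the list did not pass (adjusted p = 0.732 with an estimated correlation, over the 31 lists). For the same comparison 15 of 16 noradrenergic genes had a positive difference, with a median of 0.13 and 0 passing over all genes or over the list alone (adjusted p = 0.754 with an estimated correlation). Beyond 2-fold lay 19 of 165 genes for deprivation in WT, 17 of 100 in CnB1KO, 4 of 7 for the genotype after sleep and 4 of 19 after deprivation.

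Averaged over sleep states, 447 genes differed between CnB1KO and WT, mostly by little, and with the oligodendrocyte score as covariate 10 passed, so part of the differences may follow how much white matter each dissected piece held. For the 447 genes the median log2 difference, in its own direction, was 0.23 with a median SE of 0.0523. Under the oligodendrocyte score it was 0.16 with a median SE of 0.0556, with all 447 in the same direction. The median difference was thus smaller and the median SE slightly larger, while what ended each call was not tested. With the cerebellar score 278 genes passed, 237 of them among the 447, but the median difference of the 447 stayed at 0.21 with a median SE of 0.05 and all in the same direction, so the lost calls do not decide on the share of cerebellum. The tables argue against library depth as the source of most of these differences. With the log2 library total as covariate 570 genes passed, 353 of them among the 447. The median difference of the 447 stayed at 0.22 with a median SE of 0.0534 and all in the same direction. Blocks of linked genes stay open, since the 267 pairs of these genes within 2 Mb lay between the median of 253 and the 95th percentile of 292 of 1000 random sets (share as large 0.275), as does an effect of calcineurin loss on the share of cell types, which was not tested apart from the dissection.

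Opalin was lower after deprivation in both genotypes, averaged by a log2 value of -1.08 with an SE of 0.10. Fewer oligodendrocytes in the deprived pieces, as its sole source, would bring this change to 0 under the oligodendrocyte score if the score followed their share in full. Opalin is 1 of the 12 members of the score. The change stayed at -0.8688 (SE 0.0986, adjusted p = 1.3e-04). It shrank from -1.28 to -0.971 in WT and from -0.875 to -0.767 in CnB1KO, so a part from fewer oligodendrocytes is not excluded. Library depth would bring the change to 0 under the log2 library total, but it stayed at -1.077 (SE 0.105, adjusted p = 1.4e-05). A response of oligodendrocytes to waking is a hypothesis that these values leave open, and the cells that carry it were not identified here.

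Each count was compared with those of other splits of the same libraries into groups of the same sizes, 100 splits per comparison with the real one. For deprivation in CnB1KO (real count 100, highest of the other splits 0) the real split alone, 1 of 100, was as large. So it was for deprivation averaged over genotypes (678, highest other 0) and the genotype after sleep (7, highest other 2). That share is the smallest that 100 splits can give, and chance is unlikely as the sole source of each of these counts taken alone. For the averaged genotype 2 of 100 splits were as large (447, highest other 732), and for deprivation in WT 4 of 100 (165, highest other 1556). Both shares lie under a limit of 5% of splits that is not corrected over the 7 comparisons, so chance is not excluded for these counts. Nor is it for the genotype after deprivation, with 6 of 100 splits as large (19, highest other 1527). For the interaction the splits decide nothing, since with a real count of 0 all 100 are as large by construction (highest other 766). Splits that call several times the real count point to a structure of the samples that the labels do not name, and which property of the libraries it follows was not tested.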
